A study of Mus musculus with 9 samples.

How the data were processed

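RNA from pachytene spermatocytes (PAC), round spermatids (RS) and elongating spermatids (ES) of wild-type mouse testis was sequenced in 9 libraries, 3 per cell type. Per the labels' extract protocol, ribosomal RNA was removed from total RNA, the RNA was fragmented and primed with random hexamers, and dUTP was used in the second strand so that strand was kept. How the cells were isolated and how many animals gave each library are not given in the sources used here. The submitters' processing notes name HISAT2, StringTie and the genome build GRCm38.p6, with no versions and no order of steps.

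The deposited count table holds estimated counts per feature, not normalised by the authors: 18.85% of its values are not whole, although its label calls them raw counts, so values were rounded to whole numbers for the tests. The authors also deposited an FPKM table of the same 50493 features, and over 3914 features with more than 500 counts the ratio of FPKM to count varied between libraries, after total depth, by an SD of 0.103 on the log2 scale. The lengths and totals behind the FPKM values are not stated. Features are of 3 kinds by their identifiers: 21877 NCBI genes, 21104 RefSeq non-coding transcripts and 7512 transcripts with MSTRG identifiers, the form that StringTie gives to assembled transcripts. Symbols, biotypes and coordinates came from a reference table of GRCm38.p6, the same build, and matched 21726 NCBI genes and 15734 RefSeq transcripts of 9606 genes. The other 5370 RefSeq transcripts and the assembled transcripts had no match, so they have no symbol or coordinates here, and whether an assembled transcript overlaps a known gene was not analysed here. RefSeq non-coding transcripts were treated as a class by identifier, and no feature with coordinates lay on the mitochondrial chromosome.

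Total counts per library ran from 22910156 to 33801617, so a floor of 3 counts in a library came to 0.0866 CPM averaged over RS, 0.104 over PAC and 0.146 over ES. Where all libraries of a cell type had no counts, a fold was given as a lower bound against that floor per library. Intervals and floors cover counting error only, since reads are not independent molecules. Features were kept by edgeR's filterByExpr with a minimum count of 10, which left 26030 and removed 24463. TMM factors scaled the libraries and ranged from 0.758 in ES replicate 1 to 1.099 in RS replicate 1. Each pair of cell types was compared with edgeR's quasi-likelihood test (two-sided, robust fit, common biological coefficient of variation 0.24), adjusted by Benjamini-Hochberg over all features tested and called at an adjusted p below 0.05. A joint F test covered the 3 cell types, and a feature was highest in a cell type when it was called higher there against both others. Levels are CPM after TMM scaling. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.

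Simulated counts with 200 changed features per comparison tested the fit. They were drawn from each feature's mean over all 9 libraries and from the libraries' own depths and dispersions. The changed features were picked from those with a mean above 1 CPM, so the shares recovered do not cover features below that level. In the simulation of RS against PAC 3% of 1.5-fold, 29.9% of 2-fold and 84.8% of 4-fold changes were recovered, with 5 false calls among 25412 features. For ES against RS the shares were 3%, 34.3% and 87.9% with 6 false calls among 25384 features, and for ES against PAC 6%, 26.9% and 87.9% with 3 false calls among 25398. With 200 features changed the Benjamini-Hochberg adjustment is stricter than in these comparisons, where many more features were called, so the shares do not give how often real changes of each size were missed.

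Gene lists were tested with limma's camera on log CPM with a preset correlation of 0.01, again with an estimated correlation, and with fry, over the 24 lists with at least 5 tested members. No list passed an adjusted p of 0.05 with the estimated correlation in any comparison. Fry passed more lists than camera. For RS against PAC it passed every list but the imprinted lncRNA (fry adjusted p = 0.125). Among those it passed was the widely expressed lncRNA (adjusted p = 0.000839 with fry and 0.298 with camera). List results below are camera's, and a list said not to pass did not pass camera with the preset correlation. The lists, written before the data were examined, were pachytene and meiotic prophase, round spermatid acrosome, spermatid chromatin condensation and tail, piRNA pathway, spermatogonia, postmeiotic sex-chromosome multicopy, Sertoli cell, Leydig cell, peritubular and vascular cell, macrophage and blood, X-inactivation centre, imprinted lncRNA, lncRNA described in testis, somatic-tissue lncRNA, widely expressed lncRNA, small nucleolar RNA host, RIKEN names from adult testis libraries and from other libraries, Gm-numbered predicted genes, antisense or opposite-strand names, microRNA host names, assembled transcripts, X-linked and Y-linked. Piwil1 and Mybl1 belong to both the meiotic and the piRNA list, and several lncRNAs belong to more than 1 list. The lists of other cell types hold genes that germ cells can also express, such as Clu, Ctsl, Vim and Ptgds. Of the symbols in the lists 26 had no feature. The assembled list was a rule on identifiers, and which libraries its members were assembled from is not stated. All 7512 assembled transcripts had counts in some library, against 12952 of 21104 RefSeq non-coding transcripts. If these libraries were the source, membership depends on the data tested. The p of that list is therefore not independent support in any comparison.

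Genes were named by a rule also fixed before the data were examined. From called features in which no library of either cell type overlapped the other and the higher type had a mean of at least 5 CPM, the rule took the 5 largest changes and the 3 most abundant in each direction, and the 2 members of each list with the smallest p. Features without a symbol were named for at most 2 per direction. Piwil1, Malat1, Neat1, Tug1, Xist, Tsx, Meg3 and any feature named Tscl1 were to be named in any case. Shares of counts were compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment, and shares of features by Fisher's exact test.

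The alternatives were DESeq2's size factors, total library size alone and upper-quartile factors in place of TMM, no filter and a stricter filter, the DESeq2 Wald test, limma on log2 FPKM with a pseudocount of 1 or 0.1 and without a filter, a replicate block, a fit on only the 2 cell types compared, non-coding transcripts normalised alone, an adjusted p below 0.01, a fold change of at least 2, and leaving out each library in turn. No library was left out of the values reported.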

Results

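RNA was sequenced from 3 kinds of male germ cell isolated from wild-type mouse testis: pachytene spermatocytes (PAC), cells in the long prophase of the first meiotic division; round spermatids (RS), the haploid cells that follow meiosis; and elongating spermatids (ES), which condense their chromatin and build the sperm tail. The libraries were made from total RNA after removal of ribosomal RNA and kept strand information, so that coding and long non-coding RNAs were measured together. Each cell type had 3 libraries, which the submitters' design text calls biological replicates. Total counts were 31174833, 25141592 and 26264100 in PAC replicates 1, 2 and 3, 30238191, 33801617 and 31436713 in RS, and 24419245, 24386451 and 22910156 in ES. The table held 50493 features: 21877 genes, 21104 RefSeq non-coding transcripts and 7512 transcripts assembled from reads. Of these, 26030 had enough counts to be tested. The series title concerns the long non-coding RNA TSCL1 and the protein PIWIL1. No feature carried the symbol Tscl1, so that transcript could not be matched and no value is given for it. It may be among the features without a symbol or under another name. Levels are scaled counts per library of a common size (CPM), as mean ± SD.

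The 3 cell types parted along the first 2 principal components, which held 56% and 27% of the variance of log CPM. Protein-coding genes took 91.2% ± 0.144 (SD, n = 3) of counts in PAC, 92.5% ± 0.091 in RS and 89.9% ± 3.37 in ES. RefSeq non-coding transcripts took 2.12% ± 0.032 in PAC, 2.57% ± 0.037 in RS and 2.25% ± 0.166 in ES. Assembled transcripts took 6.33% ± 0.132, 4.51% ± 0.056 and 7.55% ± 3.26. ES replicate 1 stood apart from the other ES libraries: assembled transcripts held 11.2% of its counts against 4.997% and 6.43% in replicates 2 and 3. Its 10 most abundant features held 14.2% against 8.85% and 8.25%. The share of the 10 most abundant features was 3.83% ± 0.263 in PAC, 4.87% ± 0.2 in RS and 10.4% ± 3.27 in ES. In the two-sided exact permutation test of these shares the smallest p that 3 libraries against 3 can give is 0.1. The RefSeq non-coding share of RS reached it against PAC (difference 0.452 percentage points) and against ES, with a Benjamini-Hochberg adjusted p of 0.15 over 18 comparisons, so none of the shares passed the test.

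The comparison of RS with PAC asked which RNAs change from the meiotic to the first postmeiotic stage. Of the gene lists, 21 of 32 genes of meiotic prophase and 18 of 25 of the piRNA pathway fell, and 15 of 25 of the acrosome and 28 of 29 of condensing chromatin and the tail rose. No such list passed with an estimated correlation (adjusted p = 0.187, 0.187, 0.195 and 0.197). Piwil1 (chromosome 5, 128736071 to 128755474, GRCm38.p6), which encodes the PIWI protein that binds pachytene piRNAs, fell from 163 ± 35.8 CPM (SD, n = 3) in PAC to 7.26 ± 1.35 in RS, a log2 fold change of -4.49 (SE 0.24, adjusted p = 1.02e-07). Tex101, a germ-cell surface glycoprotein gene on chromosome 7, fell from 251 ± 52.3 to 12.4 ± 2.56 CPM (log2 fold change -4.34, adjusted p = 5.56e-08). Tssk6, which encodes a testis-specific serine kinase of spermatids, rose from 88.0 ± 20.5 to 626 ± 47.5 CPM (log2 fold change 2.83, adjusted p = 3.45e-07). Catsper3, a subunit gene of the calcium channel of the sperm tail, rose from 27.0 ± 2.66 to 93.3 ± 5.80 CPM (log2 fold change 1.79, adjusted p = 7.71e-07).

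Among the pachytene and meiotic prophase genes, 21 of 32 fell and 3 rose in RS, with a median log2 fold change of -1.27 (adjusted p = 2.89e-05). The adjusted p = 0.187 with an estimated correlation. In the piRNA pathway 18 of 25 genes fell and 2 rose, with a median of -1.76 (adjusted p = 1.51e-05; adjusted p = 0.187 with an estimated correlation). Mov10l1, the RNA helicase gene needed to make piRNAs, went from 135 ± 17.9 CPM (SD, n = 3) to 21.7 ± 1.002. The spermatid chromatin condensation and tail genes rose in 28 of 29 cases, with a median of 2.18 (adjusted p = 2.26e-08; adjusted p = 0.197 with an estimated correlation). Cabs1, which encodes a calcium-binding protein of spermatids, went from 163 ± 29.5 to 1120 ± 97.8 CPM. Of 25 genes of the round spermatid acrosome list, which also holds the Catsper channel genes of the tail, 15 rose and 3 fell, with a median of 1.57 (adjusted p = 0.00167; adjusted p = 0.195 with an estimated correlation). Eqtn, which encodes a protein of the acrosomal membrane, went from 121 ± 10.8 to 372 ± 35.6 CPM.

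**Figure D1:**
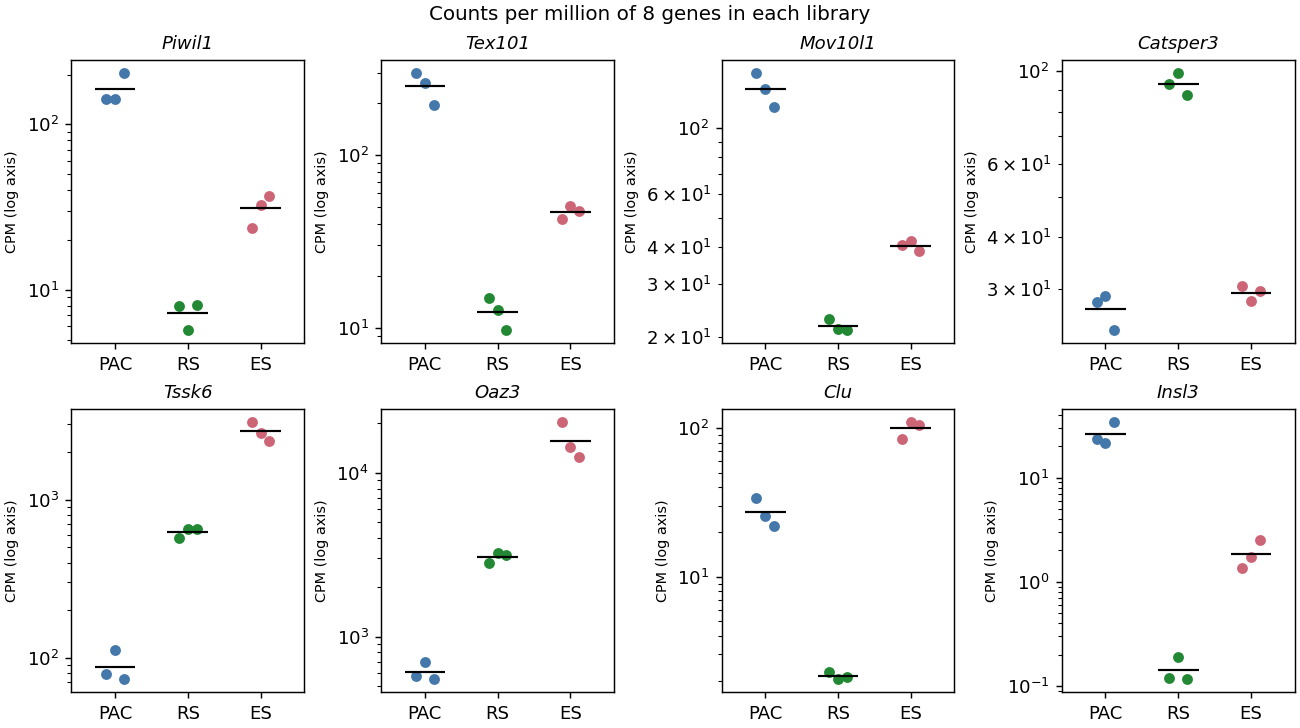
Levels in CPM, on a log axis, of 8 genes in each library of pachytene spermatocytes (PAC), round spermatids (RS) and elongating spermatids (ES); each point is 1 library and each bar the mean of 3. Piwil1, Tex101, Mov10l1, Clu and Insl3 were lowest in RS, Catsper3 was highest in RS, and Tssk6 and Oaz3 were highest in ES.

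The most abundant genes that rose in RS were Crisp2, Fhl4 and Gstm5, and those that fell included Eef1a1 and Mroh4. Crisp2, a cysteine-rich secretory protein gene of sperm, went from 4494 ± 524 CPM (SD, n = 3) to 6713 ± 489 (adjusted p = 0.00653). Fhl4 went from 4734 ± 573 to 6700 ± 277 (adjusted p = 0.0121). Gstm5, a glutathione transferase gene, had an adjusted p of 0.0186 and a log2 fold change of 0.53. It was no longer past the threshold without PAC replicate 3 (0.42), RS replicate 2 (0.51) or RS replicate 3 (0.52). Mroh4 fell from 2239 ± 265 to 816 ± 17.6 CPM (adjusted p = 2.85e-06). The translation elongation factor gene Eef1a1 fell by 0.53 on the log2 scale (adjusted p = 0.00945), though only by 0.22 and below the threshold with upper-quartile scaling. Among the largest changes, 1700094D03Rik and the unnamed RefSeq transcript XR_001778088.1 had no counts in PAC and 12.4 ± 6.27 and 12.2 ± 3.37 CPM in RS, at least 120-fold and at least 118-fold higher. Gm15093, on the X chromosome, went from 0.414 ± 0.717 to 15.5 ± 1.98 CPM. Its counts in PAC, 34.4, lay in replicate 2 alone, and its log2 fold change of 5.27 was 4.64 without PAC replicate 1. Without replicate 2 PAC had no counts of Gm15093, so the fitted 11.79 there gives no size of change. The non-coding Rsf1os1 went from 0.578 ± 0.251 to 7.07 ± 1.09. The assembled transcript MSTRG.24141.2 went from 0.205 ± 0.265 to 6.85 ± 0.931, a log2 fold change of 5.08 that was 4.45 without PAC replicate 1 and 6.96 without PAC replicate 3. The assembled transcripts MSTRG.15141.6 and MSTRG.15141.5 had 249 ± 17.02 and 57.2 ± 24.1 CPM in PAC and no counts in RS, at least 2870-fold and at least 661-fold lower. MSTRG.15141.3, by its identifier of the same assembled locus, had 61.6 CPM in PAC and 3.51 in RS. Both bounds are thus for single transcripts, not for the locus. Timm29, a gene of a mitochondrial import complex, had 12.8 ± 2.03 CPM in PAC and no counts in RS, at least 148-fold lower. These bounds use a floor of 3 counts per library and cover counting error only.

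Markers of cells other than germ cells also differed between RS and PAC. Of the Sertoli cell genes 15 of 17 fell in RS, with a median log2 fold change of -2.03 (adjusted p = 0.00053; adjusted p = 0.344 with an estimated correlation). Clu went from 27.1 ± 6.16 CPM (SD, n = 3) to 2.15 ± 0.127, and Ctsl, a cathepsin gene, from 20.2 ± 9.68 to 3.15 ± 0.560. Of the Leydig cell genes 9 of 10 fell, with a median of -6.14, or -5.90 with the gene that had no counts in RS set at its bound (adjusted p = 1.06e-05; adjusted p = 0.123 with an estimated correlation). Insl3, the gene of a Leydig cell peptide hormone, went from 26.3 ± 6.83 to 0.143 ± 0.0419 CPM, and Ptgds, a prostaglandin synthase gene, from 20.9 ± 2.602 to 0.422 ± 0.0423. The Leydig list holds the paralogs Hsd3b1 and Hsd3b6, whose shared reads cannot be assigned with certainty. Of the macrophage and blood genes 7 of 13 rose and 2 fell (adjusted p = 0.0783). Among them C1qb went from 0.984 ± 0.181 to 6.44 ± 0.0735 CPM. Of the peritubular and vascular genes 6 of 10 rose and 1 fell (adjusted p = 0.103). Dcn went from 1.61 ± 0.462 to 10.3 ± 4.23 CPM. Of the spermatogonia genes 9 of 17 fell and 2 rose (adjusted p = 0.0507). The list passed the test with total counts alone (median -0.55), upper-quartile factors (-0.29), no filter (-0.58), the stricter filter (-0.88), a replicate block (-0.634) or FPKM with a pseudocount of 0.1 (-0.61). It also passed without PAC replicate 1 (-0.66) or 3 (-0.76), RS replicate 1 (-0.91) or 2 (-0.89), or ES replicate 2 (-0.60) or 3 (-0.59). Id4, a transcription regulator gene of that list, went from 86.7 ± 13.5 to 6.99 ± 0.734 CPM, and Gfra1, a receptor subunit gene for the growth factor GDNF, from 10.2 ± 0.586 to 24.8 ± 1.15.

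Non-coding transcripts moved mostly up where coding genes moved mostly down. In RS 1888 of 4295 RefSeq non-coding transcripts rose and 861 fell, with a median log2 fold change of 1.01. Normalised alone, 1254 rose and 1006 fell, with a median of 0.57. Of the assembled transcripts 4090 of 6704 rose and 1017 fell, with a median of 1.47. Of 14836 protein-coding genes 3901 rose and 6962 fell, with a median of -0.46. The assembled list had an adjusted p of 7.41e-10 (adjusted p = 0.123 with an estimated correlation). Its members may have been assembled from these same reads, so that p is not independent support. Features with RIKEN names from adult testis libraries rose in 530 of 873 cases and fell in 151 (adjusted p = 1.06e-05; adjusted p = 0.187 with an estimated correlation). Those named from other libraries rose in 77 of 341 cases and fell in 152 (adjusted p = 0.0107; adjusted p = 0.167 with an estimated correlation). Predicted genes with Gm numbers rose in 1379 of 2813 cases and fell in 475 (adjusted p = 0.000227; adjusted p = 0.0565 with an estimated correlation). The last 2 lists lost their call with no filter on low counts, where their medians were -0.135 and 0.578, and from FPKM with no filter (-0.002 and 0.012).

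Of 17 small nucleolar RNA host transcripts 14 fell in RS, with a median of -1.91 (adjusted p = 0.000382; adjusted p = 0.197 with an estimated correlation). Mir17hg, listed with them though it is the host of a microRNA cluster, went from 9.18 ± 0.661 CPM (SD, n = 3) to 0.282 ± 0.0857. Snhg3 went from 17.2 ± 2.70 to 3.18 ± 0.510. Norad, a cytoplasmic RNA that binds Pumilio proteins, went from 139 ± 18.7 to 25.1 ± 2.01 CPM (log2 fold change -2.47, adjusted p = 1.05e-06). Neat1, the architectural RNA of paraspeckles, fell in its transcript NR_003513.3 from 15.2 ± 2.78 to 1.40 ± 0.392 CPM (log2 fold change -3.43, adjusted p = 9.35e-07), and its overlapping transcript NR_131212.1 had a log2 fold change of -1.46 (adjusted p = 0.087). It passed the threshold without PAC replicate 1 (-1.81) or ES replicate 3 (-1.45), with a replicate block (-1.274) and in a fit of PAC and RS alone (-1.46). Tug1 fell in its transcript NR_002322.2 from 50.9 ± 11.7 to 17.5 ± 1.26 CPM (adjusted p = 0.000458). Its transcript NR_002321.2 had a log2 fold change of 0.35 (adjusted p = 0.115; past the threshold at 0.51 without PAC replicate 3 and at 0.66 with upper-quartile factors) and NR_110490.1 of -0.43 (adjusted p = 0.12; -0.66 and past the threshold without RS replicate 3). Short reads divide overlapping transcripts of 1 gene uncertainly. Malat1 had 290 ± 165 CPM in PAC and 131 ± 9.32 in RS (adjusted p = 0.0645). It passed the threshold without PAC replicate 1 (-1.45), ES replicate 1 (-1.14) or ES replicate 3 (-1.14). It also passed with DESeq2's size factors (-1.19), with a replicate block (-0.936) and in a fit of PAC and RS alone (-1.15). Xist and Meg3 had too few counts to be tested in any comparison. The imprinted lncRNA list had 3 of 6 members lower and 1 higher (adjusted p = 0.566), with Mirg falling from 17.5 ± 6.26 to 2.43 ± 0.476 CPM and Peg13 rising from 5.15 ± 2.56 to 13.3 ± 0.629. The lists of lncRNA described in testis (2 of 5 fell, adjusted p = 0.341), somatic-tissue lncRNA (3 of 8 fell and 1 rose, adjusted p = 0.427), widely expressed lncRNA (8 of 22 fell and 3 rose, adjusted p = 0.298), antisense or opposite-strand names (33 of 82 rose and 18 fell, adjusted p = 0.171) and microRNA host names (1 of 5 fell, adjusted p = 0.8; median 0.33 but mean -0.71) did not pass the test.

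Features of the sex chromosomes were mostly higher in RS, while the median autosomal gene was lower. Of 718 X-linked features 409 rose and 135 fell, with a median log2 fold change of 1.24 (adjusted p = 2.15e-05; adjusted p = 0.197 with an estimated correlation). Of 201 Y-linked features 176 rose and 0 fell, with a median of 1.82 (adjusted p = 2.79e-15; adjusted p = 0.123 with an estimated correlation). Among protein-coding genes alone the medians were 1.13 on X, 1.81 on Y and -0.53 on the autosomes. Many Y genes and some X genes belong to multicopy families whose reads cannot be assigned to 1 copy with certainty. In the list of such postmeiotic genes 6 of 8 rose (adjusted p = 0.0216; adjusted p = 0.167 with an estimated correlation), a call that was lost without PAC replicate 2 (median 1.53) or 3 (1.58), RS replicate 2 (1.41) or 3 (1.56), or ES replicate 3 (1.46), and from FPKM with a pseudocount of 0.1 (1.38). Slxl1, a relative of Slx, went from 7.21 ± 0.961 CPM (SD, n = 3) to 27.1 ± 1.24, and Zfy1, a zinc finger gene of the Y chromosome, from 4.71 ± 1.201 to 14.3 ± 1.10. In the X-inactivation centre list 4 of 5 features rose and 1 fell (adjusted p = 0.306): Zcchc13 rose from 15.8 ± 3.59 to 79.0 ± 5.51 CPM and Tsx, an X-linked testis gene annotated as protein-coding, fell from 5.55 ± 2.55 to 1.71 ± 0.270.

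In all, 9956 of 26030 features were higher in RS and 8907 lower at an adjusted p below 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 8818 and 6749 of these changed at least 2-fold. Adjusted over the list alone, the counts of features that rose and fell were 535 and 152 for the RIKEN testis names, 76 and 148 for the other RIKEN names, 1341 and 466 for the Gm numbers, 4107 and 1023 for the assembled transcripts, 411 and 136 on X, 176 and 1 on Y, and 3 and 7 for the widely expressed lncRNA. For the other lists the counts adjusted over the list alone were those given.

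**Figure D2:**
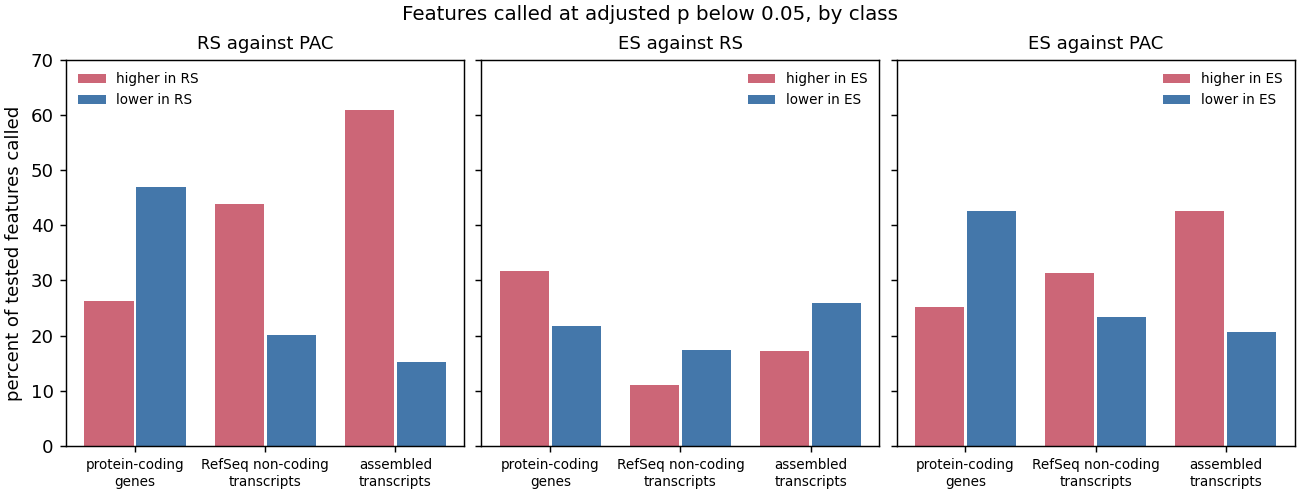
Percent of the tested features of each class that were higher (red) or lower (blue) at an adjusted p below 0.05 in each comparison of cell types; bars start at 0. In RS against PAC 61% of assembled transcripts were higher, and coding genes were more often lower than higher.

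The comparison of ES with RS asked which RNAs change as spermatids elongate. Of the gene lists, 21 of 29 genes of condensing chromatin and the tail rose, 20 of 25 of the acrosome fell, and 17 of 17 markers of Sertoli cells and 10 of 13 of macrophages and blood rose in the same libraries. No such list passed with an estimated correlation (adjusted p = 0.514, 0.0723, 0.169 and 0.0546). Oaz3, which encodes a haploid-specific antizyme of the sperm tail, rose from 3053 ± 224 CPM (SD, n = 3) in RS to 15730 ± 4164 in ES (log2 fold change 2.37, SE 0.19, adjusted p = 5.45e-06), and Crisp2 rose from 6713 ± 489 to 17740 ± 3280 (adjusted p = 4.3e-05). Catsper3 fell from 93.3 ± 5.80 to 29.4 ± 1.21 CPM (log2 fold change -1.67, adjusted p = 4.79e-06). Clu, abundant in Sertoli cells, rose from 2.15 ± 0.127 to 99.99 ± 13.5 CPM (log2 fold change 5.54, adjusted p = 1.73e-07). Piwil1 rose from 7.26 ± 1.35 to 31.1 ± 6.86 CPM (log2 fold change 2.10, SE 0.22, adjusted p = 2.47e-05).

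Of the spermatid chromatin condensation and tail genes 21 of 29 rose in ES and 1 fell, with a median log2 fold change of 1.14 (adjusted p = 9.31e-05; adjusted p = 0.514 with an estimated correlation). Tssk6 went from 626 ± 47.5 CPM (SD, n = 3) to 2701 ± 376. Of the round spermatid acrosome genes 20 of 25 fell, with a median of -1.02 (adjusted p = 1.18e-07; adjusted p = 0.0723 with an estimated correlation), among them Spam1, the gene of the sperm surface hyaluronidase, from 180 ± 10.1 to 66.1 ± 2.47 CPM. The pachytene and meiotic prophase genes had 12 of 32 higher and 5 lower (adjusted p = 0.293), and the piRNA pathway 8 of 25 higher and 5 lower (adjusted p = 0.473). Syce2, a gene of the central element of the synaptonemal complex, went from 137 ± 7.02 to 483 ± 49.9 CPM, Tex101 from 12.4 ± 2.56 to 46.8 ± 4.19, and Tdrd1, a Tudor domain gene of the piRNA pathway, from 10.2 ± 0.207 to 42.1 ± 13.9. The medians of these 2 lists, 0.31 and 0.20, fell below 0 when libraries were scaled by total counts alone. Of the spermatogonia genes 9 of 17 rose and 2 fell (adjusted p = 0.0228; adjusted p = 0.224 with an estimated correlation). Id4 went from 6.99 ± 0.734 to 18.2 ± 1.65 CPM and Uchl1, a ubiquitin hydrolase gene, from 1.33 ± 0.166 to 5.06 ± 0.942. Beside these changes stand the somatic markers: the median Sertoli gene was higher in ES by 4.90 on the log2 scale.

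Sertoli cell genes rose in ES in 17 of 17 cases (adjusted p = 9.7e-12; adjusted p = 0.169 with an estimated correlation). Wt1, a transcription factor gene of Sertoli cells, went from 0.124 ± 0.0298 CPM (SD, n = 3) to 8.56 ± 1.56. Of the Leydig cell genes 9 of 10 rose, with a median of 3.17, or 2.92 with the gene that had no counts in RS set at its bound (adjusted p = 9.31e-05; adjusted p = 0.135 with an estimated correlation). Among them Ptgds went from 0.422 ± 0.0423 to 12.3 ± 1.99 CPM. Macrophage and blood genes rose in 10 of 13 cases (adjusted p = 2.41e-05; adjusted p = 0.0546 with an estimated correlation). The globin genes Hba-a2 and Hbb-bs went from 0.242 ± 0.0688 to 32.5 ± 7.65 and from 1.13 ± 0.394 to 85.3 ± 19.4 CPM. Each has a near-identical paralog, so the copy is uncertain. Peritubular and vascular genes had 2 of 10 higher and 3 lower (adjusted p = 0.696). Vwf, the von Willebrand factor gene, went from 3.87 ± 0.515 to 12.04 ± 0.565 CPM (log2 fold change 1.64, adjusted p = 0.0012), a call lost from FPKM with a pseudocount of 0.1 (0.93).

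**Figure D3:**
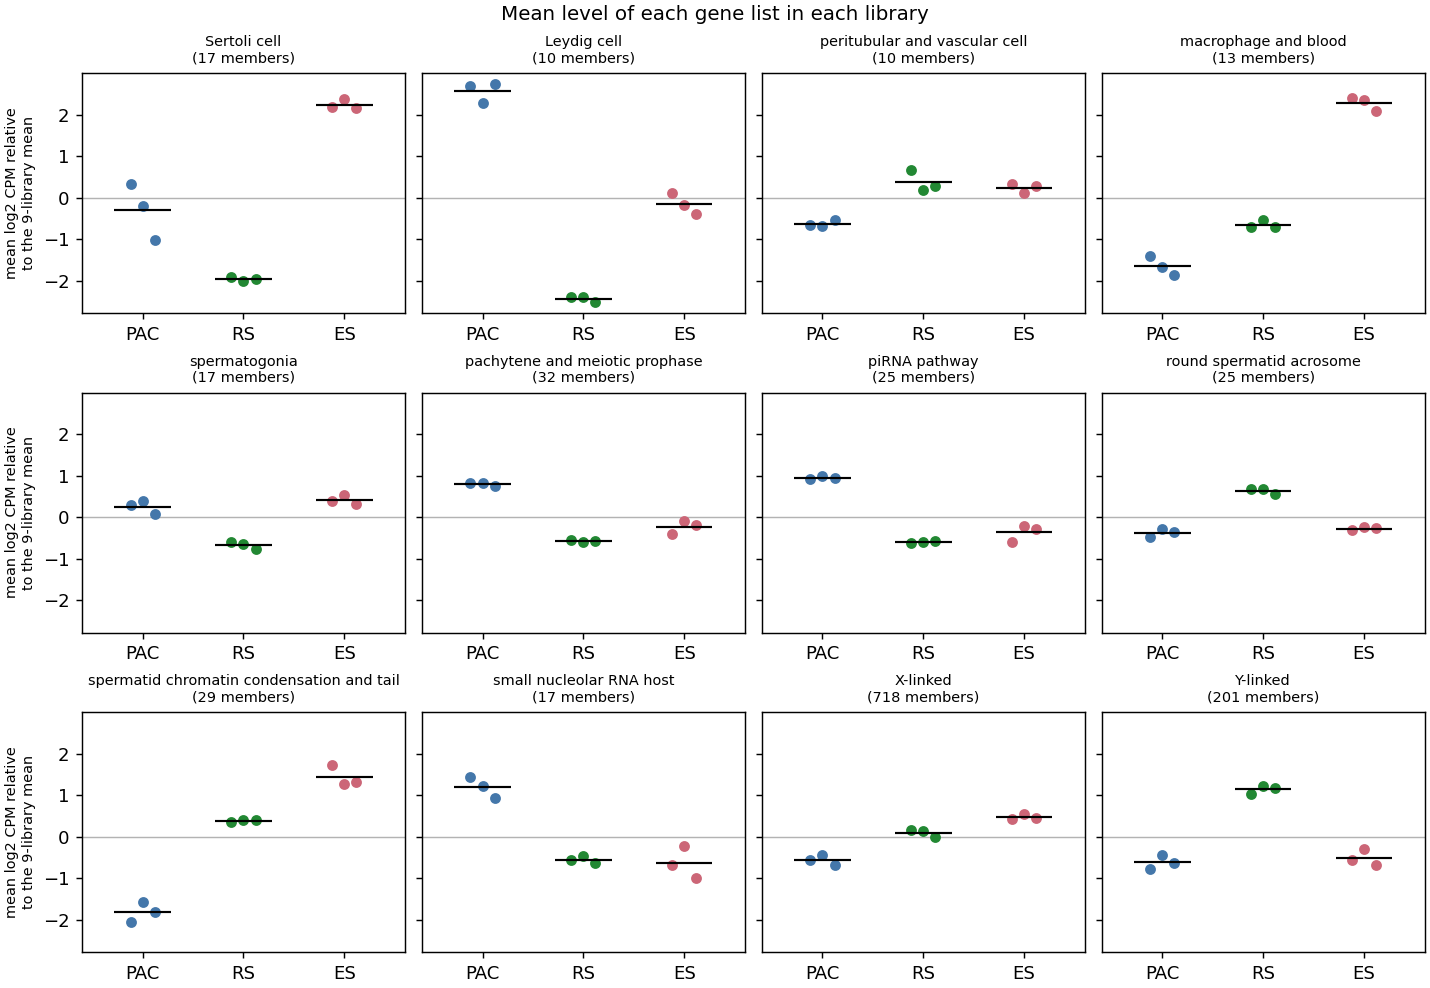
Mean log2 CPM of the members of 12 gene lists in each library, relative to the mean of the 9 libraries; each point is 1 library and each bar the mean of 3. The Sertoli cell and the macrophage and blood lists were highest in the ES libraries, and the Leydig cell list was highest in the PAC libraries.

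The abundant genes that fell in ES were Tcp1, Mael and Lrrc34. Lrrc34 fell from 1774 ± 106 CPM (SD, n = 3) to 618 ± 39.0 (adjusted p = 8.1e-06). Mael, a piRNA pathway gene, fell by 0.54 on the log2 scale (adjusted p = 0.00648) and was below the threshold with DESeq2's size factors. Tcp1, a chaperonin subunit gene, fell by 0.36 (adjusted p = 0.032), a call lost without RS replicate 1 (-0.38), 2 (-0.38) or 3 (-0.36), without ES replicate 2 (-0.38) or 3 (-0.32), with DESeq2's size factors (-0.21) or upper-quartile factors (-0.36), in DESeq2's Wald test (-0.23) and in a fit of RS and ES alone (-0.32). Gstm5 rose from 5137 ± 320 to 13660 ± 2976 CPM (adjusted p = 8.92e-05). Among the largest changes, the assembled transcripts MSTRG.7694.4 and MSTRG.7693.2 had no counts in RS and 36.2 ± 38.1 and 31.8 ± 31.0 CPM in ES, at least 417-fold and at least 367-fold higher. ES replicate 1 carried most of both means: it held 1471 counts of MSTRG.7694.4 against 175 and 449 in replicates 2 and 3, and 1245 of MSTRG.7693.2 against 230 and 379. Without it both bounds would be lower, and the log2 fold changes were 11.74 and 11.69 in place of 12.99 and 12.80. As RS had no counts, the fitted log2 fold changes of these 2 transcripts give no size of change, and only the bounds do. Both calls were lost without ES replicate 3 (log2 fold changes 13.29 and 13.12) and with no filter on low counts. MSTRG.22607.2 had 21.0 ± 8.69 CPM in RS and no counts in ES, at least 144-fold lower. MSTRG.22607.3, by its identifier of the same assembled locus, had 8.90 CPM in RS and 1.01 in ES. The features 1700094D03Rik and XR_001778088.1 had no counts in ES, at least 85-fold and at least 84-fold lower than in RS. The predicted gene Gm34678 went from 5.30 ± 2.44 to 0.352 ± 0.217 CPM.

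With TMM scaling non-coding transcripts fell in ES more often than they rose, a balance that depended on the scaling and the test. Of 4295 RefSeq non-coding transcripts 476 rose and 745 fell, against 587 and 636 with DESeq2's size factors, 643 and 649 in its Wald test, 373 and 432 when normalised alone, and 289 and 1130 with total counts alone. With TMM 1149 of 6704 assembled transcripts rose and 1731 fell. In contrast 4719 of 14836 coding genes rose and 3220 fell. The assembled list had a median of -0.16 (adjusted p = 0.0228; adjusted p = 0.514 with an estimated correlation). The call was lost without ES replicate 2 (-0.12) or 3 (-0.11), with total counts alone (-0.49) and with FPKM and a pseudocount of 1 (-0.25) or 0.1 (-0.47). The features with Gm numbers had 288 of 2813 higher and 726 lower (adjusted p = 0.000422; adjusted p = 0.0546 with an estimated correlation), a call lost with no filter on low counts and in the fits to FPKM. The RIKEN testis names had 137 of 873 higher and 249 lower (adjusted p = 0.0205; adjusted p = 0.514 with an estimated correlation), a call lost without ES replicate 3 (-0.21). The other RIKEN names had 72 of 341 higher and 66 lower (adjusted p = 0.888, camera's direction down but median 0.025 and mean 0.13). In the list of lncRNA described in testis 4 of 5 features rose (adjusted p = 0.0228; adjusted p = 0.155 with an estimated correlation), a call lost without ES replicate 3 (0.81). The 5 features belong to 3 genes. Those that rose were Tsx, annotated as protein-coding, from 1.71 ± 0.270 CPM (SD, n = 3) to 57.6 ± 3.06, the X-linked testis lncRNA Tslrn1, named after its values were seen, from 0.0571 ± 0.0585 to 2.23 ± 0.502 (adjusted p = 0.000257), and transcripts of Tug1. With 1 library left out Tsx rose by 4.98 to 5.19 on the log2 scale, near the Sertoli list's median of 4.90. Whether its rise arose within germ cells was not tested. NR_002321.2 of Tug1 rose from 52.9 ± 2.40 to 105 ± 20.4 (adjusted p = 0.00133), a call lost from FPKM with no filter (0.60). NR_110490.1 had a log2 fold change of 0.66 (adjusted p = 0.0421), past the threshold in the full set but not without PAC replicate 2 (0.64) or 3 (0.63), RS replicate 1 (0.45) or 2 (0.62), or ES replicate 2 (0.68) or 3 (0.45), and not with total counts alone (0.35), no filter (0.61) or FPKM. Norad rose from 25.1 ± 2.01 to 57.8 ± 13.4 CPM (adjusted p = 0.000287). Oip5os1, also named Cyrano, rose from 8.94 ± 1.29 to 16.9 ± 0.935 (adjusted p = 0.000714). Peg13 fell from 13.3 ± 0.629 to 4.40 ± 0.769 CPM (adjusted p = 0.00207). Malat1 (adjusted p = 0.467), Neat1 NR_003513.3 (0.634), Neat1 NR_131212.1 (0.848) and Tug1 NR_002322.2 (0.651) did not pass the test. The lists of small nucleolar RNA hosts (1 of 17 rose and 1 fell, adjusted p = 0.771), widely expressed lncRNA (5 of 22 rose and 1 fell, adjusted p = 0.888), somatic-tissue lncRNA (1 of 8 rose and 1 fell, adjusted p = 0.696), imprinted lncRNA (1 of 6 rose and 1 fell, adjusted p = 0.696; median -0.48 but mean 0.70), antisense names (11 of 82 rose and 13 fell, adjusted p = 0.531; median 0.018 but mean -0.12) and microRNA hosts (1 of 5 fell, adjusted p = 0.234) did not pass either.

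Y-linked features fell in 156 of 201 cases in ES and rose in 5, with a median log2 fold change of -1.71 (adjusted p = 2.91e-23; adjusted p = 0.0546 with an estimated correlation). X-linked features had 249 of 718 higher and 217 lower, with a median of 0.22 (adjusted p = 0.696), which turned to -0.094 with scaling by total counts alone. Of the postmeiotic multicopy genes 6 of 8 fell and 1 rose (adjusted p = 0.0228; adjusted p = 0.148 with an estimated correlation). Slxl1 went from 27.1 ± 1.24 CPM (SD, n = 3) to 10.7 ± 1.62 and Zfy1 from 14.3 ± 1.10 to 5.70 ± 0.515. That call was lost without any 1 of the PAC or RS libraries (medians -1.29 to -1.36) or without ES replicate 3 (-1.27), and from FPKM with a pseudocount of 1 (-0.85) or 0.1 (-1.46). In the X-inactivation centre list 2 of 5 rose (adjusted p = 0.473). Among them Zcchc13 went from 79.0 ± 5.51 to 162 ± 48.6 CPM.

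In all, 6374 features were higher in ES than in RS and 5752 lower at an adjusted p below 0.05, and 4613 and 3473 of these changed at least 2-fold. With 1 library left out they ranged from 4976 to 6625 and from 4647 to 6173. Of the features that passed, 52.6% were higher, against 34.4% when libraries were scaled by total counts alone, which moved the median of all features from 0.048 to -0.28, and 32.8% from the FPKM table with a pseudocount of 1. Adjusted over the list alone, the counts that rose and fell were 136 and 245 for the RIKEN testis names, 69 and 63 for the other RIKEN names, 255 and 689 for the Gm numbers, 11 and 12 for the antisense names, 1108 and 1674 for the assembled transcripts, 265 and 226 on X, 6 and 161 on Y, 1 and 0 for the small nucleolar RNA hosts and 4 and 1 for the widely expressed lncRNA, and for the other lists they were those given.

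The comparison of ES with PAC spanned the whole course from meiosis to elongation. In ES 27 of 29 genes of condensing chromatin and the tail were higher, 25 of 32 of meiotic prophase and 20 of 25 of the piRNA pathway lower, and 17 of 17 Sertoli markers and 11 of 13 macrophage and blood markers higher. None of these lists passed with an estimated correlation (adjusted p = 0.211, 0.211, 0.211, 0.325 and 0.134). Tssk6 rose from 88.0 ± 20.5 CPM (SD, n = 3) in PAC to 2701 ± 376 in ES (log2 fold change 4.94, SE 0.20, adjusted p = 2.22e-08) and Oaz3 from 609 ± 80.0 to 15730 ± 4164 (log2 fold change 4.69, adjusted p = 3.66e-08). Piwil1 fell from 163 ± 35.8 to 31.1 ± 6.86 CPM (log2 fold change -2.39, SE 0.22, adjusted p = 3.68e-06). Meioc, a gene that keeps germ cells in meiotic prophase, fell from 598 ± 75.9 to 147 ± 20.6 CPM (log2 fold change -2.02, adjusted p = 7.68e-07).

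Of the spermatid chromatin condensation and tail genes 27 of 29 rose, with a median log2 fold change of 3.73 (adjusted p = 9.56e-12; adjusted p = 0.211 with an estimated correlation). Among them Cabs1 went from 163 ± 29.5 CPM (SD, n = 3) to 4828 ± 988. Of the pachytene and meiotic prophase genes 25 of 32 fell and 3 rose, with a median of -1.06 (adjusted p = 6.97e-05; adjusted p = 0.211 with an estimated correlation). Syce2, named for its role in the synaptonemal complex, went the other way, from 48.2 ± 6.16 to 483 ± 49.9 CPM. In the piRNA pathway 20 of 25 fell and 1 rose, with a median of -1.52 (adjusted p = 7.92e-06; adjusted p = 0.211 with an estimated correlation). Tdrd12 went from 292 ± 46.0 to 67.5 ± 8.97 CPM and Mov10l1 from 135 ± 17.9 to 40.4 ± 1.62. The acrosome list had 10 of 25 higher and 8 lower (adjusted p = 0.644). Spaca9 went from 18.9 ± 3.84 to 106 ± 33.7 CPM and Izumo4 from 159 ± 20.5 to 77.5 ± 1.44. The spermatogonia list had 4 of 17 higher and 2 lower (adjusted p = 0.644), with Dmrtb1, the gene of a DM domain transcription factor, going from 622 ± 69.99 to 262 ± 5.95 CPM and Id4 from 86.7 ± 13.5 to 18.2 ± 1.65.

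Sertoli cell genes rose in 17 of 17 cases, with a median log2 fold change of 2.51 (adjusted p = 4.12e-06; adjusted p = 0.325 with an estimated correlation). Aard went from 5.54 ± 2.93 CPM (SD, n = 3) to 48.4 ± 3.38 and Clu from 27.1 ± 6.16 to 99.99 ± 13.5. Macrophage and blood genes rose in 11 of 13 cases, with a median of 4.15 (adjusted p = 7.92e-06; adjusted p = 0.134 with an estimated correlation). Among them Hbb-bs went from 0.501 ± 0.239 to 85.3 ± 19.4 CPM and Hba-a2 from 0.172 ± 0.0928 to 32.5 ± 7.65. Leydig cell genes fell in 9 of 10 cases, with a median of -3.23 (adjusted p = 0.000283; adjusted p = 0.211 with an estimated correlation). Insl3 went from 26.3 ± 6.83 to 1.86 ± 0.590 CPM and Fabp3, a fatty acid binding protein gene, from 17.1 ± 1.96 to 1.99 ± 0.541. Peritubular and vascular genes had 4 of 10 higher and 1 lower (adjusted p = 0.285), with Vwf at 2.06 ± 1.04 CPM in PAC and 12.04 ± 0.565 in ES and Dcn at 1.61 ± 0.462 and 7.05 ± 1.35.

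X-linked features rose in 365 of 718 cases and fell in 11, with a median of 0.92 (adjusted p = 1.95e-10; adjusted p = 0.211 with an estimated correlation). Among protein-coding genes the median was 0.95 on X and -0.47 on the autosomes. Y-linked features had 19 of 201 higher and 6 lower, with a median of 0.12 (adjusted p = 0.404). The postmeiotic multicopy genes had 3 of 8 higher (adjusted p = 0.341). Zfy2 went from 5.11 ± 1.12 CPM (SD, n = 3) to 11.9 ± 0.733 and Slxl1 from 7.21 ± 0.961 to 10.7 ± 1.62 (adjusted p = 0.0105, a call lost with scaling by total counts alone, at 0.27, and in the 3 fits to FPKM, at 0.27, 0.29 and 0.27). In the X-inactivation centre list 3 of 5 rose (adjusted p = 0.0468; adjusted p = 0.211 with an estimated correlation). That call was lost without PAC replicate 1 (median 1.92), RS replicate 1 (2.34) or 3 (2.34), or ES replicate 2 (1.76), and with upper-quartile factors (2.64), no filter (1.60), or FPKM and a pseudocount of 1 with the filter (0.51) or without it (0.031), and the median of 2.35 was 3.37 without PAC replicate 2. Zcchc13 rose from 15.8 ± 3.59 to 162 ± 48.6 CPM and Tsx from 5.55 ± 2.55 to 57.6 ± 3.06.

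**Figure D4:**
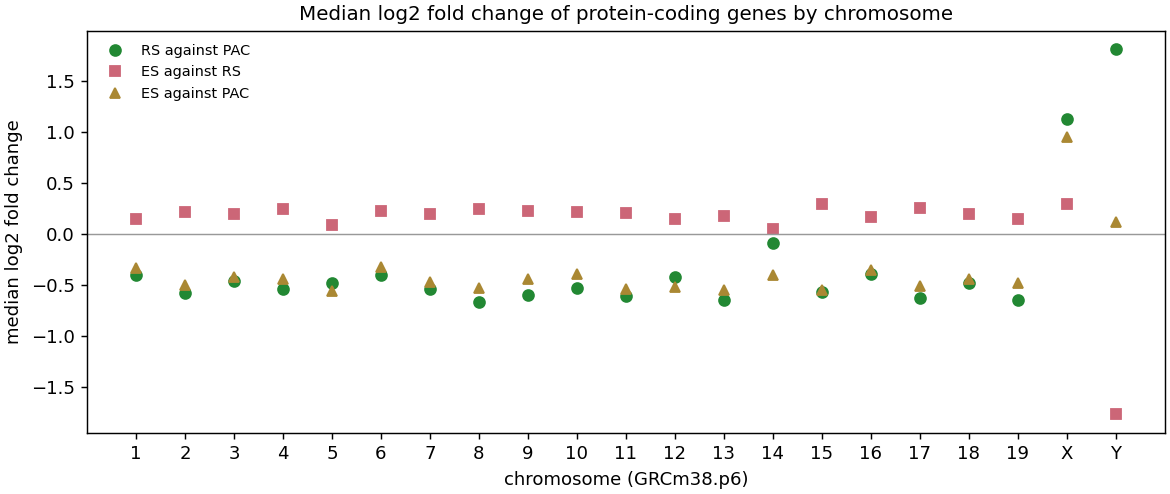
Median log2 fold change of protein-coding genes on each chromosome (horizontal axis) in the 3 comparisons; each symbol is 1 chromosome. In RS against PAC the medians were 1.13 on X and 1.81 on Y, and in ES against RS the Y median was -1.77.

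From PAC to ES 1348 of 4295 RefSeq non-coding transcripts rose and 1003 fell, 2852 of 6704 assembled transcripts rose and 1387 fell, and 3741 of 14836 coding genes rose and 6323 fell. Which way the RefSeq non-coding balance lay depended on the scaling: 1159 rose and 1209 fell with total counts alone and 1055 and 1106 when normalised alone, but 1427 and 947 with DESeq2's size factors and 1614 and 793 with upper-quartile factors. From FPKM with a pseudocount of 1 it was 1452 and 1415 with the filter and 1452 and 1549 without it, and 1513 and 1436 with the filter and a pseudocount of 0.1. The assembled list had a median of 0.53 (adjusted p = 0.000185; adjusted p = 0.257 with an estimated correlation). The assembled transcript MSTRG.26573.1 had 0.392 ± 0.334 CPM (SD, n = 3) in PAC and 7156 ± 6297 in ES, with 265458, 59229 and 94915 counts in ES replicates 1, 2 and 3. MSTRG.26570.1 went from 0.0104 ± 0.018 to 398 ± 356 CPM, with 14894, 3266 and 5170 counts in ES replicates 1, 2 and 3. Their log2 fold changes of 14.09 and 14.61 were 13.08 and 13.60 without ES replicate 1, and 15.07 and 16.41 without PAC replicate 1. The PAC level of MSTRG.26570.1 lay below the floor of 0.104 CPM, so its log2 fold changes give no sure size. MSTRG.20881.4 and the unnamed RefSeq transcript XR_866714.2 had 159 ± 36.1 and 127 ± 14.3 CPM in PAC and no counts in ES, at least 1091-fold and at least 871-fold lower. MSTRG.20881.3, by its identifier of the same assembled locus as MSTRG.20881.4, had 294 CPM in PAC and 22.4 in ES. The bound for MSTRG.20881.4 is thus for a single transcript, not for the locus. The RIKEN testis names rose in 356 of 873 cases and fell in 200 (adjusted p = 0.00976; adjusted p = 0.409 with an estimated correlation), a call lost from FPKM with no filter (median 0.05). The other RIKEN names rose in 61 of 341 and fell in 148 (adjusted p = 0.00721; adjusted p = 0.211 with an estimated correlation), lost with no filter on low counts (-0.035) and from FPKM with no filter (-0.007). Small nucleolar RNA hosts fell in 13 of 17 cases and rose in 1, with a median of -1.98 (adjusted p = 0.000847; adjusted p = 0.257 with an estimated correlation), with Mir17hg at 0.226 ± 0.0538 CPM in ES and Snhg5 going from 9.34 ± 1.39 to 1.73 ± 0.435. Neat1 NR_003513.3 fell from 15.2 ± 2.78 to 1.58 ± 0.269 CPM (adjusted p = 1.52e-06). Its transcript NR_131212.1 had an adjusted p of 0.0706. It was past the threshold without PAC replicate 1 (-2.02) or ES replicate 3 (-2.94), with a replicate block (-1.847) and from FPKM with a pseudocount of 1 (-0.39) or 0.1 (-1.38). Tug1 rose in NR_002321.2 (1.34, adjusted p = 8.35e-05), fell in NR_002322.2 (-1.38, adjusted p = 0.00103) and did not pass in NR_110490.1 (adjusted p = 0.436). Malat1 had 94.3 ± 58.5 CPM in ES (log2 fold change -1.62, adjusted p = 0.0194), a call lost without PAC replicate 3 (-1.09) or ES replicate 2 (-1.58) and with no filter on low counts (-1.64). Kcnq1ot1, an imprinted antisense RNA, went from 68.5 ± 33.4 to 19.4 ± 15.8 CPM (adjusted p = 0.0164), also lost without PAC replicate 3 (-1.40) or ES replicate 2 (-1.61) and with no filter (-1.84), and at -2.71 without ES replicate 3, from -1.82. Mirg fell to 3.94 ± 1.65 CPM (adjusted p = 0.000267) and Oip5os1 rose from 5.49 ± 0.0817 to 16.9 ± 0.935 (adjusted p = 7.17e-06).

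The lists of lncRNA described in testis (3 of 5 rose and 1 fell, adjusted p = 0.245), imprinted lncRNA (2 of 6 fell, adjusted p = 0.463), widely expressed lncRNA (10 of 22 fell and 3 rose, adjusted p = 0.426), somatic-tissue lncRNA (2 of 8 fell, adjusted p = 0.644), Gm numbers (775 of 2813 rose and 630 fell, adjusted p = 0.404), antisense names (25 of 82 rose and 21 fell, adjusted p = 0.404) and microRNA hosts (2 of 5 fell, adjusted p = 0.284) did not pass the test from PAC to ES. Among the abundant genes Crisp2, Oaz3 and Gstm5 rose. Tcp1 and Mael fell by 0.57 and 0.61 on the log2 scale (adjusted p = 0.00154 and 0.00183) and were below the threshold with upper-quartile scaling (-0.27 and -0.31) and in a fit of PAC and ES alone (-0.38 and -0.42). In all, 7976 features were higher in ES than in PAC and 8778 lower, 6850 and 6269 of them by at least 2-fold. With 1 library left out they ranged from 7624 to 7962 and from 8238 to 8904. Of the features that passed, 47.6% were higher, against 57.9% with upper-quartile scaling, which moved the median of all features from -0.093 to 0.212. Adjusted over the list alone, the counts that rose and fell were 11 and 8 for the acrosome genes, 3 and 2 for the spermatogonia genes, 4 and 0 for the X-inactivation centre, 61 and 147 for the other RIKEN names, 738 and 584 for the Gm numbers, 2850 and 1382 for the assembled transcripts, 355 and 11 on X and 8 and 0 on Y, and for the other lists they were those given.

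Across the 3 cell types together 21353 of 26030 features changed, which is 82% of those tested. The features highest in PAC against both other types numbered 6618, those highest in RS 3486 and those highest in ES 3465. With 1 library left out they ranged from 5991 to 6662, from 2782 to 3632 and from 2674 to 3528. The balance of RS and ES depended on the processing. Those highest in RS and in ES numbered 4398 and 2283 with total counts alone, and 3053 and 4011 with DESeq2's size factors. From FPKM with a pseudocount of 1 and the filter they numbered 5453 and 3008. Of the coding genes 4937 were highest in PAC, 1581 in RS and 2185 in ES, and of the RefSeq non-coding transcripts 719, 510 and 342. By Fisher's exact test, which treats features as independent, non-coding transcripts were less often highest in PAC than coding genes (odds ratio 0.403, adjusted p = 1.7e-104) and in ES (0.501, adjusted p = 1.73e-33), and somewhat more often highest in RS (1.13, 95% confidence interval 1.014 to 1.257, adjusted p = 0.0263). These odds are over all tested features. Non-coding transcripts were called less often than coding genes: 64% against 73.2% in RS against PAC, 28.4% against 53.5% in ES against RS and 54.7% against 67.8% in ES against PAC. The odds ratios therefore mix how often a feature was called with its stage, and do not measure a stage preference alone. Levels fell at both steps for 847 features and rose at both for 2046. Piwil1 was highest in PAC, lowest in RS and between them in ES. Whether its higher level in ES than in RS arose within elongating spermatids or from RNA of pachytene spermatocytes in those libraries cannot be told apart here.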

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

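All comparisons rest on 3 libraries per cell type. Simulated 2-fold changes were recovered in 26.9% to 34.3% of cases when 200 features with a mean above 1 CPM changed. That does not give the share missed where many more changed or at lower levels. No list or named feature past the threshold turned its sign under an alternative that was run. Of the 19 counts and X-linked medians that answer the comparisons, 9 kept their sign and, for counts, stayed within 1.5 times of their value under all alternatives, as did 393 of 417 values. Of the 69 list results 38 kept their direction and side of the threshold throughout, and of the 140 named features 112. Each list and feature whose sign turned had an adjusted p above 0.05 with TMM as well. The cause was not tested, except that a stricter threshold or fewer features lowers counts by construction. In every paragraph values are medians of log2 fold changes for lists and log2 fold changes for features.

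With libraries scaled by total counts alone, the non-coding transcripts higher and lower in ES than in RS numbered 289 and 1130, and 2283 features were highest in ES. For ES against RS the X-linked median was -0.094, Neat1 NR_003513.3 was at -0.165, Tug1 NR_002322.2 at -0.129, and the lists at -0.001 (meiotic prophase), -0.125 (piRNA pathway), -0.289 (widely expressed lncRNA), -0.135 (X-inactivation centre), -0.319 (other RIKEN names) and -0.328 (antisense names). For ES against PAC Tug1 NR_110490.1 was at -0.043, the acrosome list at -0.046, the Gm numbers at -0.188, the antisense names at -0.11 and the Y-linked list at -0.162. This scaling moved the median of all features to 0.155, -0.28 and -0.377 for RS against PAC, ES against RS and ES against PAC, from 0.113, 0.048 and -0.093. Upper-quartile factors moved it to 0.421, 0.045 and 0.212, and the somatic-tissue lncRNA and microRNA host lists to 0.268 and 0.062 for ES against PAC. DESeq2's size factors moved it to 0.057, 0.189 and -0.008, with the small nucleolar RNA hosts at 0.092 for ES against RS and the somatic-tissue lncRNA at 0.041 for ES against PAC, and 61% of the features called between ES and RS were then higher.

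In limma on log2 FPKM with a pseudocount of 1, 9154 features and 1509 non-coding transcripts were lower in ES than in RS and 5453 features were highest in RS. With a pseudocount of 0.1, 4202 features were higher and 8861 lower in ES than in RS, and 1426 non-coding transcripts were lower. With a pseudocount of 1 and no filter these counts were 4225, 8699 and 1445, and 1549 non-coding transcripts were lower in ES than in PAC. The percent higher among features called between ES and RS was 32.8, 32.2 and 32.7 in these 3 fits. For ES against RS they gave, in the same order, X-linked medians of -0.028, -0.108 and -0.001, Neat1 NR_003513.3 at -0.051, -0.121 and -0.051, Tug1 NR_002322.2 at -0.154, -0.241 and -0.154, meiotic prophase at -0.05, -0.054 and -0.05, the piRNA pathway at -0.149, -0.234 and -0.143, widely expressed lncRNA at -0.057, -0.205 and -0.022, the X-inactivation centre at -0.068, -0.165 and -0.008, and antisense names at -0.124, -0.206 and -0.019. The other RIKEN names were at -0.061 and -0.248 in the filtered fits. For ES against PAC they gave Tug1 NR_110490.1 at -0.049, -0.065 and -0.049, the Y-linked list at -0.076, -0.151 and -0.016, the Gm numbers at -0.001 and -0.014 in the filtered fits, and antisense names at -0.034 with the pseudocount of 0.1. For RS against PAC the microRNA hosts were at -0.045, -0.222 and -0.017.

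With no filter on low counts the microRNA hosts were at -0.898 for RS against PAC, the imprinted lncRNA at 0.201 and the peritubular and vascular genes at 0.426 for ES against RS, and the widely expressed lncRNA at 0.029 for ES against PAC. The stricter filter gave the somatic-tissue lncRNA 0.092 for RS against PAC, and for ES against RS the widely expressed lncRNA -0.089, the other RIKEN names -0.031 and the antisense names -0.126. A fit on only the 2 cell types compared gave the other RIKEN names -0.055 for ES against RS and the somatic-tissue lncRNA 0.169 for ES against PAC. With non-coding transcripts normalised alone, which left the median of that class at 0.569 for RS against PAC, 1254 were higher in RS than in PAC and 432 lower in ES than in RS. At an adjusted p below 0.01, 243 non-coding transcripts were higher and 440 lower in ES than in RS, and 2200 features were highest in ES. With a fold change of at least 2, 3473 features were lower in ES than in RS and 4390 were highest in PAC.

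The labels do not say what a replicate number shares. After group means were removed, libraries numbered 1, 2 and 3 correlated with their own number across features, which are not independent replicates, at -0.016, 0.025 and 0.106 between PAC and RS, 0.185, -0.024 and 0.273 between PAC and ES, and 0.034, -0.04 and 0.068 between RS and ES. Libraries of different numbers correlated at -0.254 to 0.094. The 2 highest values belong to PAC and ES libraries of the same number, but not every library correlated best with its own number, so the numbers were not taken to pair the libraries. With the replicate number as a replicate block 10117 features were higher and 8950 lower in RS than in PAC, 6407 and 5968 in ES against RS, and 8025 and 8981 in ES against PAC. With the block Malat1 (-0.936), Neat1 NR_131212.1 (-1.274) and the spermatogonia list (-0.634) for RS against PAC and Neat1 NR_131212.1 (-1.847) for ES against PAC passed the threshold, where they had not without it, and no other list or named feature changed its side of the threshold. For ES against RS the block gave the widely expressed lncRNA -0.018, the other RIKEN names -0.041 and the antisense names -0.045.

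When each library was left out in turn, features higher and lower ranged from 9021 to 10374 and from 7947 to 9396 for RS against PAC, from 4976 to 6625 and from 4647 to 6173 for ES against RS, and from 7624 to 7962 and from 8238 to 8904 for ES against PAC. For ES against RS the antisense names then ranged from -0.167 to 0.045, the other RIKEN names from -0.047 to 0.055, the peritubular and vascular genes from -0.518 to 0.042, the widely expressed lncRNA from -0.065 to 0.165, the small nucleolar RNA hosts from -0.242 to 0.107, Neat1 NR_003513.3 from -0.045 to 0.324, Neat1 NR_131212.1 from -1.488 to 0.267, and Tug1 NR_002322.2 from -0.045 to 0.448. For ES against PAC the somatic-tissue lncRNA ranged from -0.368 to 0.37 and the microRNA hosts from -1.071 to 0.025.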

Other observations

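Abundant genes of PAC that nearly vanished in RS were not all in the fixed lists. Among 128 coding genes with at least 20 CPM in PAC and less than 10% of that in RS, H1f6, the testis-specific linker histone gene, went from 1699 ± 447 CPM (SD, n = 3) in PAC to 16.7 ± 0.690 in RS and 274 ± 29.9 in ES. The histone genes H2bc1 and H2ax went from 606 ± 136 to 12.3 ± 3.90 and from 219 ± 37.5 to 11.4 ± 3.05 CPM in RS, with 133 ± 33.1 and 49.0 ± 9.19 in ES. Cyp19a1, which encodes aromatase, went from 1220 ± 98.2 to 17.6 ± 2.39 and then 71.4 ± 7.01 CPM, and C2cd4b from 1430 ± 125 to 20.3 ± 2.81 and then 85.8 ± 17.3. All of these passed edgeR's quasi-likelihood test in RS against PAC and in ES against RS, and all were chosen after their values were seen: H1f6, C2cd4b and Cyp19a1 as the 3 most abundant of the 128, and H2bc1 and H2ax as further histone genes.

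Of the tests reported here, those of the germ cell share, of pachytene RNA in ES and of the splits of libraries were chosen only after the result was seen, and the bounds of the tests of pachytene RNA were also altered after their results. Sertoli markers were higher in ES than in RS by a median of 4.90 on the log2 scale. A further list of 12 Sertoli genes, written before their values were looked at, gave a median of 4.67 over its 10 tested members (quartiles 4.08 to 4.96). Of these 9 rose, such as Nr5a1 from 0.366 to 10.4 CPM. A lower share of germ cells that raises every other cell type alike was argued against, since the Sertoli median stood 5.41 above that of the peritubular and vascular genes (permutation p = 6e-05). That p treats genes as independent, though the Sertoli genes had an estimated correlation of 0.606. The peritubular and vascular list was already seen not to rise when the test was chosen. The Leydig and the macrophage and blood lists did rise, with medians of 3.17 and 1.68. Only an equal rise of every other cell type is thus argued against, and a lower germ cell share with an unequal rise was not tested. RNA of Sertoli cells in the ES libraries stays open as a hypothesis and may account for the Sertoli markers, of which Clu was highest at 99.99 CPM. A change within the germ cells was not tested, and no sort or gate is described in the sources used here.

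Coding genes high in PAC that nearly vanished in RS were by their means partly back in ES, while the meiotic prophase and piRNA lists did not pass the test in ES against RS (adjusted p = 0.293 and 0.473). Over the 128 coding genes, picked by level alone and so including somatic markers such as Insl3, Ptgds and Clu, the median return, the gain from RS to ES as a share of the loss from PAC to RS, was 16.8% (quartiles 12.5 to 22.7), with Neb below RS, and Acsbg1 and Clu above PAC. RNA of pachytene spermatocytes as the whole of the return would bring every abundant transcript back by about that share, and was argued against. Of 140 other features of the same levels in PAC and RS, 122 of them assembled transcripts, 50.7% (95% confidence interval 42.1 to 59.3) returned by less than 5.6%. The intervals in this paragraph treat features as independent. Several of the 140 are transcripts of the same assembled locus by their identifiers, so that interval is likely too narrow. The 20 most abundant coding genes returned by a median of 13.2% and the other 108 by 17.7%, a ratio of 1.34 (permutation p = 0.016). The ratio lay within its bound of 1.5, but the explanation also required a p above 0.05. That test thus met neither its condition for nor its condition against the explanation, and it decides nothing. A smaller share of pachytene RNA stays open, since only 3.9% of the coding genes (5 of 128, namely C2cd4b, Cyp19a1, Chst1, Neb and Vcam1, interval 1.3 to 8.9) returned by less than 5.6%. Yet MSTRG.20881.4, XR_866714.2 and MSTRG.15141.5, at 159, 127 and 57.2 CPM in PAC, had no counts in ES, where short reads divide overlapping transcripts uncertainly. Such a share of pachytene RNA and a rise within elongating spermatids cannot be told apart for the 128 coding genes, because the cell types were not measured in known mixtures. Piwil1 was 1 of these genes, with a return of 15.3%.

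RefSeq non-coding transcripts were higher and coding genes lower in RS than in PAC, with medians 1.47 apart on the log2 scale. The low level of the non-coding transcripts was argued against as the cause, since the gap was 1.76 (SE 0.056) against coding genes of the same mean level. Counting by transcript was argued against as well, since the gap was 1.46 (SE 0.05) with transcripts summed into 2593 genes, of which 1265 rose and 580 fell. A scaling factor moves both classes alike and so cannot make the gap, and more non-coding transcripts rose than fell with DESeq2's size factors (1831 and 894), total counts alone (1918 and 823) and upper-quartile factors (2169 and 693), and by less when normalised alone (1254 and 1006, median 0.57). A difference between the cell types themselves stays open as a hypothesis and was not tested further.

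The 6 libraries of each pair of cell types can be split in 10 ways, too few for a share under 0.05. For RS against PAC 1 of the 10 splits, the real one, gave as many features as the 18863 called, with at most 0 in any other, and likewise 1 for the 2749 non-coding transcripts, with at most 0. For ES against RS the real values were 12126 and 1221 and for ES against PAC 16754 and 2351, each reached by 1 of 10 splits with at most 0 in any other. Across the 3 cell types 1 of 100 splits drawn from 280 gave as many as the 21353 features, the real one, with 10979 at most in the others. Libraries of the same cell type correlated at 0.966 to 0.992 and those of different types at 0.799 to 0.919. The real split was thus bound to call the most, and the count shows only that the libraries group by cell type. It does not tell cell type from preparation or batch, whose layout is not given in the sources used here.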
